A study of Mus musculus with 114 samples.

How the data were processed

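RNA was measured by sequencing in 114 libraries from 45 mice of the NZB/W F1 lupus model. They comprise 38 spleens, 40 kidneys and 36 blood samples from 8 treatment groups. Spleen and kidney came from the same animal in 38 mice, all 3 tissues in 29 mice, and 5 mice gave blood only. The labels give 50 bp reads, 1 µg of input RNA, 8 PCR cycles, 5 libraries per lane and a plan of 30 M reads per library (M is the mega unit).

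The deposited table of each library holds counts of reads over the exons of each gene, which the authors made with GSNAP against the mouse build mm9, per the submitters' processing notes. Those notes also name DESeq2 1.4.5 without saying what it was used for. The deposited RPKM values divide each count by the exon width and by 1 total per library. That total was 0.586 to 1.189 times the sum of the counts, as found from the values themselves, and RPKM entered no test here. The gene annotation is not stated. Rows carry NCBI gene identifiers, and gene coordinates on mm9 were not used here because no annotation of that build was at hand.

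Each library had 28096 gene rows, of which 25035 were given a symbol from the reference gene table and 3061 had none. Rows with no symbol held 4.05% to 39.73% of a library's counts. The highest shares were in blood, where 1 such row held 19.0% to 26.08%. Total counts were 10.8 to 28.19 M per spleen library (median 22.33 M), 16.16 to 33.19 M per kidney library and 9.84 to 15.19 M per blood library. The 10 globin rows took 39.22% to 51.32% of the blood counts, which left 2.31 to 6.3 M counts outside the globin rows and that unnamed row. Reads carry no molecular identifiers, so the floors given with counts of 0 cover counting error only.

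Counts were tested in R 4.3.3 with edgeR 4.0.16 by its robust quasi-likelihood test, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each tissue was fitted once with all 8 groups, TMM factors and the filterByExpr filter by group. This left 17196 genes in spleen, 17562 in kidney and 11499 in blood. Biological coefficients of variation were 26.2%, 25.7% and 37.8%. TMM factors lay between 0.850 and 1.14 in spleen, 0.887 and 1.15 in kidney, and 0.299 and 5.22 in blood. The median log2 fold change of all genes tested lay between -0.10 and 0.04 in each comparison, and size factors of the RLE kind moved it by at most 0.05. Unless a sentence says otherwise, expression is the group mean of TMM-normalised counts per M reads (CPM) with its SD, each change is a log2 fold change with its standard error (SE), and an adjusted p comes from the edgeR test. A gene is said to be called when its adjusted p is under 0.05.

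Counts were also simulated from the gene means, library sizes and trended spread of the real data, with known changes planted. The simulated genes vary independently and hold no outlying library, so the rates need not hold in the real libraries. On these counts the edgeR test recovered 65% of 2-fold and 96% of 4-fold changes in spleen, 69% and 94% in kidney, and 11% and 84% in blood. Wrong calls made up 1.2%, 8.4% and 7.8% of all calls in those tests. Between replicate libraries, 219 pairs were compared and 0 were identical. The pairing of spleen and kidney by mouse was checked over 16045 genes: the median correlation of a mouse's deviations from its group means was 0.0819 within a mouse and -0.0388 between mice of the same group. Since the labels give the same animal, the difference of the BTK inhibitor effect between spleen and kidney was also fitted with the mouse as a block.

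The comparisons were interferon day 21 against naive, vehicle against naive, vehicle against interferon day 21, each inhibitor against vehicle, 1 inhibitor against the other, mBR3 against anti-ragweed, and Cytoxan against vehicle, each in all 3 tissues. The groups, the tests, 30 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover plasma cells, the unfolded protein response, immunoglobulin constant genes, B lymphocytes, germinal centre cells, follicular helper T cells, B cell receptor signalling, activation and immediate early genes, type I interferon targets, macrophages and monocytes, neutrophils, erythroid cells, T cells, natural killer and cytotoxic cells, dendritic cells, basophils and mast cells, platelets, proliferation, p53 targets, complement and Fc receptors, chemokines and cytokines, tubular injury, fibrosis, podocytes, proximal tubule, distal nephron, mitochondrial energy metabolism, exocrine pancreas, adipose tissue and adrenal cortex. Of their 474 genes, 13 had no row, namely all 12 immunoglobulin constant genes and Ahsp. The immunoglobulin constant list therefore gave no result, with 0 of its 12 genes measured.

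Each list was tested with camera of limma 3.58.1 on voom values with a correlation between genes preset to 0.01, and again with the correlation estimated from the data. Its p was adjusted over the lists of a comparison. The members called were counted over all genes tested and adjusted over the list alone. The named genes are a panel of 31 genes, up to 4 called members of each list with the smallest p, and up to 5 genes in each direction with the largest fold changes (3 outside the BTK inhibitor and vehicle against naive comparisons). The largest changes needed a mean of at least 5 CPM and groups that did not overlap, and predicted genes, pseudogenes and antigen receptor segments were left out. Outside this rule, the marker genes Kap, Cyp11b1 and Clps were chosen after their values were seen. A disease signature was scored per library as the mean log2 CPM (prior count 2) of the genes raised at least 2-fold in anti-ragweed over naive mice minus that of the genes lowered as far. Vehicle over naive mice gave the signature for the mBR3 comparison. Disease is a label here, since neither signature separates it from a possible effect of the interferon adenovirus. Scores were compared by 2-sided exact permutation tests, adjusted over 8 tests.

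The alternatives chosen beforehand were RLE factors, no filter, a filter of 1 CPM in 5 libraries, the DESeq2 1.42.0 Wald test, limma voom with sample weights, a fit of the 2 groups alone, each library left out in turn, a term for the run code of the deposited data, anti-ragweed as control, vehicles split between the inhibitors, the mouse as a block, and other signature genes. Alternatives chosen after seeing the data were leaving out the globin rows, sets of libraries that stood apart, and covariates for adrenal or pancreatic transcripts. For each comparison of groups of at least 3 libraries, the count of called genes was set against up to 100 other splits of the same libraries. The labels give 4 weeks of treatment in the series design and 8 weeks in the treatment protocol, and which of them applies is open. They do not say whether the treated groups received the interferon adenovirus. The codes R2191 to R2194, called run codes here, come from the names of the deposited data and not from the labels. What they stand for is not stated, so reading them as sequencing runs is an assumption.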

Results

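The series was collected to study how G7744, a small-molecule inhibitor of Bruton's tyrosine kinase (BTK), acts in NZB/W F1 mice, a strain that develops lupus. RNA was sequenced from spleen, kidney and blood of 8 groups. They were naive mice, mice labelled as given an adenovirus with interferon alpha and sampled at day 21, vehicle (HPMC in citrate), the BTK inhibitor at 100 mg/kg, the SYK inhibitor G955 at 60 mg/kg, the antibody anti-ragweed IgG2a, mBR3 IgG2a (BR3 is the receptor of the B cell survival factor BAFF), and Cytoxan (cyclophosphamide, an alkylating drug). Each group had 5 libraries per tissue, except that naive spleen, SYK inhibitor spleen and mBR3 blood had 4 and anti-ragweed blood had 2. Total counts were 10.8 to 28.19 M per spleen, 16.16 to 33.19 M per kidney and 9.84 to 15.19 M per blood library.

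Mice with the interferon adenovirus were compared with naive mice to show the response at day 21. No group had an adenovirus without interferon, so virus and interferon are not separated. In the spleen at day 21, Irf7 (gene identifier 54123), a transcription factor of the interferon response, rose from 127 ± 37.5 CPM (SD, n = 4) to 1430 ± 443 CPM (SD, n = 5), a log2 change of 3.49 (SE 0.47, adjusted p = 1.2e-05). Of the 30 interferon targets, 28 rose (29 adjusted over the list alone) with a median change of 2.17, among them Ifit1 (3.21, SE 0.69), Ifi44 (4.35, SE 0.72) and Zbp1 (2.18, SE 0.29). The list passed camera with adjusted p = 2.04e-45 at the preset correlation and adjusted p = 0.0412 with an estimated correlation. Germinal centre genes rose in 3 of 9 cases (5 adjusted over the list alone), among them S1pr2, a receptor that holds B cells in the germinal centre (1.39, SE 0.34), and Nuggc (1.99, SE 0.53). That list had adjusted p = 8.29e-05 at the preset and adjusted p = 0.354 with an estimated correlation. Ly6c2 of inflammatory monocytes rose by 3.84 (SE 0.42), the cytotoxic granule gene Gzmb by 3.07 (SE 0.56) and the plasma cell factor Xbp1 by 1.21 (SE 0.35). The dendritic cell gene Cd209a fell by 2.99 (SE 0.73). Adipose genes fell in 2 of 9 cases (7 adjusted over the list alone; median -2.38; adjusted p = 0.000165, adjusted p = 0.354 with an estimated correlation), namely Fabp4 (-1.34, SE 0.37) and Lep (-3.01, SE 0.89). In all, 719 genes rose and 262 fell. The count of 981 became 419 without naive mouse 437, 511 without naive 439, 481 without interferon mouse 253 and 613 without 274. Under the alternatives other than leaving out 1 library, it ran from 811 to 5797.

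The kidneys of the same group gave 192 genes that rose and 7 that fell. Interferon targets again led: 27 of 30 rose (30 adjusted over the list alone), with a median of 2.68, adjusted p = 1.35e-69 at the preset and adjusted p = 0.00554 with an estimated correlation. Isg15 (gene identifier 100038882), a ubiquitin-like protein, rose from 12.2 ± 1.91 to 212 ± 88.6 CPM (SD, n = 5 each; 4.12, SE 0.65), and Bst2, which tethers budding virus, rose by 3.34 (SE 0.44). None of the 16 tubular injury genes was called by edgeR, with a median of 0.12. In blood, 119 genes rose and 31 fell, and 23 of 30 interferon targets rose (29 adjusted over the list alone; median 3.03; adjusted p = 3.46e-51 at the preset and adjusted p = 0.0206 with an estimated correlation). Irf7 rose there from 157 ± 90 to 4220 ± 3180 CPM (SD, n = 5 each; 4.74, SE 0.96), and the complement gene Cfb rose by 3.81 (SE 0.62). Kidney transcripts fell in this blood: 1 of 13 proximal tubule genes (10 adjusted over the list alone; median -1.46; adjusted p = 2.09e-12, adjusted p = 0.0826 with an estimated correlation) and 2 of 7 distal nephron genes (3 adjusted over the list alone; median -1.15; adjusted p = 1.67e-08, adjusted p = 0.0784 with an estimated correlation). Kap, a kidney transcript, had 0 counts in the blood of interferon mouse 360, which has another run code. It had 6.38 to 14.7 CPM of library total in the other 4 interferon libraries and 7.53 to 19.5 in the naive ones, all 9 of 1 run code. The kidney count of 199 was 131 without naive mouse 436. It ran from 187 to 3416 under the alternatives other than leaving out 1 library. The blood count of 150 was 79, 82, 88 and 87 without naive mice 438, 439, 436 and 437, and 83 without interferon mouse 360, the 1 library of these 10 with another run code.

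Vehicle mice were compared with naive mice to describe the state in which the drugs were tested. Whether vehicle mice received the interferon adenovirus is not stated, so disease and virus are not separated here. In the spleen, 962 genes rose and 669 fell. Irf7 rose by 3.55 (SE 0.47), and 29 of 30 interferon targets rose (29 adjusted over the list alone; median 2.17; adjusted p = 1.69e-38 at the preset and adjusted p = 0.0581 with an estimated correlation). Monocyte and macrophage genes rose in 14 of 22 cases (16 adjusted over the list alone; adjusted p = 1.16e-13 at the preset, adjusted p = 0.0581 with an estimated correlation). They include Fcgr1, a receptor for immunoglobulin G (2.49, SE 0.33), Ly6c2, at 504 ± 225 against 51.1 ± 11.9 CPM (SD, n = 5 and 4), and the complement receptor Vsig4 (2.94, SE 0.49). Xbp1 rose from 303 ± 88.2 (SD, n = 4) to 786 ± 104 CPM (SD, n = 5), and plasma cell genes rose in 5 of 16 cases (8 adjusted over the list alone; adjusted p = 1.99e-06 at the preset, adjusted p = 0.315 with an estimated correlation). The complement and Fc receptor list rose in 8 of 14 cases (10 adjusted over the list alone), with Fcgr4 at 90.3 ± 7.99 against 19.9 ± 3.42 CPM (SD, n = 5 and 4). Its adjusted p = 8.29e-08 became adjusted p = 0.118 with an estimated correlation. Neutrophil genes fell in 11 of 16 cases (11 adjusted over the list alone; median -1.90; adjusted p = 5.31e-12, adjusted p = 0.112 with an estimated correlation): S100a9, a calcium-binding alarmin, fell from 182 ± 46.6 to 43.2 ± 14 CPM (SD, n = 4 and 5). Adipose genes fell in 6 of 9 cases (6 adjusted over the list alone), with adjusted p = 0.000665 at the preset and adjusted p = 0.272 with an estimated correlation. Adipoq stood at 6.05 ± 4.14 CPM (SD, n = 4) in naive and 0.458 ± 0.202 CPM (SD, n = 5) in vehicle spleens. The count of 1631 was 940, 1067 and 1056 without naive mice 437, 439 and 440.

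Vehicle kidneys differed from naive kidneys in 5339 genes, of which 2744 rose and 2595 fell. Lcn2 (gene identifier 16819), a protein released by damaged tubules, rose from 8.93 ± 4.53 to 306 ± 187 CPM (SD, n = 5 each; 5.10, SE 1.00, adjusted p = 0.000356). Spp1, which encodes osteopontin, rose from 2030 ± 214 to 11800 ± 4110 CPM (SD, n = 5 each), and Vcam1, an endothelial adhesion molecule, by 2.89 (SE 0.64). Tubular injury genes rose in 12 and fell in 1 of 16 cases (15 and 1 adjusted over the list alone; median 1.73; adjusted p = 1.98e-05, adjusted p = 0.464 with an estimated correlation). All 30 interferon targets rose (median 2.98; adjusted p = 3.51e-26, adjusted p = 0.438 with an estimated correlation). Chemokines and cytokines rose in 12 of 18 cases (12 adjusted over the list alone), led by Ccl7 (4.82, SE 0.89) and Ccl2, which draws monocytes (3.56, SE 0.68). Complement genes rose in 9 of 14 (10 adjusted over the list alone), with C3 at 390 ± 216 against 64.9 ± 27.2 CPM (SD, n = 5 each). Proximal tubule genes fell in 8 of 21 cases (9 adjusted over the list alone), among them the endocytic receptor Lrp2 (-1.62, SE 0.37). Mitochondrial genes fell in 12 of 20 (14 adjusted over the list alone). These 4 lists had adjusted p = 2.75e-05, 6.67e-05, 1.98e-05 and 1.98e-05 at the preset, and each had adjusted p = 0.464 with an estimated correlation. Adrenal genes moved with these groups: all 8 rose (8 adjusted over the list alone; median 8.26; adjusted p = 0.551 with an estimated correlation). Cyp11b1, an enzyme of corticosterone synthesis, stood at 123 ± 94.1 CPM in vehicle and 0.0788 ± 0.112 CPM in naive kidneys (SD, n = 5 each). With a covariate for adrenal transcripts, chosen after seeing the data, the injury genes rose in 12 of 16 cases, with a median of 1.89, as did 12 chemokines and all 30 interferon targets. The mitochondrial and proximal tubule genes that fell went from 12 to 6 and from 8 to 5, with medians of -0.52 and -0.61.

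In blood of vehicle mice most interferon targets and part of the erythroid and monocyte genes were higher than in naive blood. Most T cell genes and part of the B cell genes were lower. Interferon targets rose in 29 of 30 cases (30 adjusted over the list alone; median 3.97; adjusted p = 2.6e-30, adjusted p = 0.0958 with an estimated correlation). T cell genes fell in 12 of 16 cases (14 adjusted over the list alone; adjusted p = 5.3e-10, adjusted p = 0.201 with an estimated correlation), as with Cd3e, a chain of the T cell receptor complex (-1.27, SE 0.30). B cell genes fell in 8 of 18 (13 adjusted over the list alone; adjusted p = 1.3e-07, adjusted p = 0.272 with an estimated correlation), as with Cd79b (-1.67, SE 0.42). Macrophage and monocyte genes rose in 8 of 20 cases (9 adjusted over the list alone; adjusted p = 2.9e-05, adjusted p = 0.229 with an estimated correlation). Erythroid genes rose in 7 of 15 cases (10 adjusted over the list alone; adjusted p = 5.68e-06, adjusted p = 0.369 with an estimated correlation), with Rhag at 15.5 ± 13.2 against 0.661 ± 0.306 CPM (SD, n = 5 each). Kidney transcripts fell: 10 of 13 proximal tubule and 7 of 7 distal nephron genes (10 and 7 adjusted over the list alone; adjusted p = 0.115 and adjusted p = 0.0958 with an estimated correlation). Kap (gene identifier 16483), an androgen-regulated protein of the proximal tubule, had 13.8 ± 5.78 CPM (SD, n = 5) in naive blood and 0 counts in vehicle blood. It was thus at least 235-fold lower against a floor of 3 counts over the group. Umod, the main protein of normal urine, was at least 65.2-fold lower. With such genes set at their bounds, the list medians were -4.87 and -4.72. All naive blood libraries carried the run code R2193 and all vehicle ones R2194. Of the 2122 called genes 1331 rose. With a term for the run code 0 were called, so treatment group and run code cannot be told apart in blood. Counts of 1249, 1256 and 3034 resulted without vehicle mouse 267, naive 436 and vehicle 391.

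**Figure D1:**
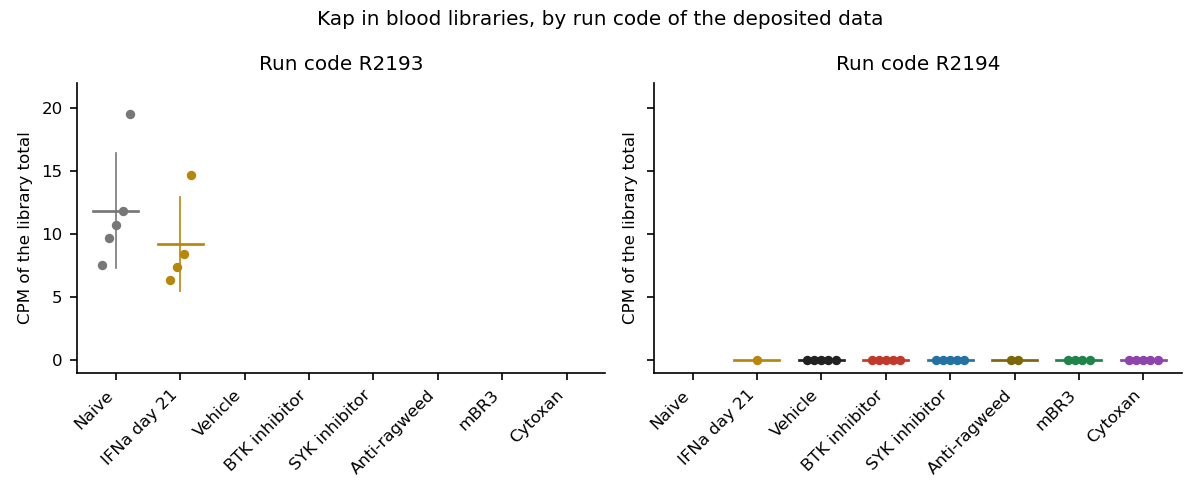
Kap in each blood library in CPM of the library total on the vertical axis, by treatment group on the horizontal axis. Each run code has its own panel, and points are coloured by treatment group. The 9 libraries with run code R2193, from naive and interferon mice, lie between 6.38 and 19.5 CPM, and the other 27 are at 0.

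Vehicle mice were also set against the interferon mice at day 21. The labels give no age or sampling day for vehicle mice. Vehicle spleens had 48 genes higher and 55 lower. Neutrophil genes fell in 12 of 16 cases (15 adjusted over the list alone; median -2.66), with adjusted p = 3.54e-37 at the preset and adjusted p = 0.00187 with an estimated correlation. S100a9 (gene identifier 20202) fell from 293 ± 92.9 to 43.2 ± 14 CPM (SD, n = 5 each), and Elane, the neutrophil elastase of early granules, from 52.4 ± 11.6 to 5.12 ± 4.07 CPM. The basophil and mast cell list fell in 4 of 9 cases (6 adjusted over the list alone; adjusted p = 0.00499 with an estimated correlation), including the basophil proteases Prss34 (-3.02, SE 0.56) and Mcpt8 (-2.91, SE 0.55). Vsig4 rose by 3.36 (SE 0.47). The count of 103 was 44 and 64 without vehicle mice 399 and 377, and 58, 61 and 64 without interferon mice 274, 359 and 371.

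In the kidney the same comparison called 5238 genes, 2727 higher and 2511 lower in vehicle mice. Tubular injury genes rose in 13 and fell in 1 of 16 cases (15 and 1 adjusted over the list alone; median 1.64), with Clu, a chaperone of injured tubules, at 1560 ± 942 against 306 ± 25.8 CPM (SD, n = 5 each). Fibrosis genes rose in 13 of 22 cases (16 adjusted over the list alone), with Col1a1 of fibrillar collagen up 1.73 (SE 0.47). The p53 targets rose in 11 of 17 (11 adjusted over the list alone), with the stress cytokine Gdf15 up 3.12 (SE 0.57). Mitochondrial genes fell in 12 of 20 cases (13 adjusted over the list alone). These 4 lists had adjusted p between 3.02e-05 and 0.000411 at the preset and adjusted p = 0.822 with an estimated correlation. Only 1 interferon target rose, with a list median of 0.36. The 8 adrenal genes were again higher in vehicle kidneys, with a median of 7.90. Their list had adjusted p = 0.00602 at the preset and adjusted p = 0.895 with an estimated correlation. The count of 5238 fell to 3303 without vehicle mouse 377. In blood, 72 genes were called. Proximal tubule genes fell in 6 of 13 and distal nephron genes in 3 of 7 cases (10 and 7 adjusted over the list alone; adjusted p = 0.24 and adjusted p = 0.155 with an estimated correlation), with list medians of -3.28 and -3.61 at the bounds. Kap was at least 72.9-fold lower and was not called (adjusted p = 0.056). B cell genes fell in 2 of 18 cases (16 adjusted over the list alone; adjusted p = 0.155 with an estimated correlation), namely Fcmr (-1.61, SE 0.37) and Cd79b (-1.74, SE 0.42). Run code divides these groups too, except for interferon mouse 360. Then 0 genes were called with a term for it, 0 with only these groups fitted, and 25 without blood 419 and 432, an alternative chosen after seeing the data. The blood count was 447 and 179 without vehicle 391 and interferon 360, and 20, 27, 28, 32, 46 and 25 without interferon 359, 357 and 371 and vehicle 267, 418 and 432.

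The comparison of BTK inhibitor with vehicle asks what differs with the drug. Spleens of treated mice had fewer transcripts of plasma cells, the cells that secrete antibody. Jchain (gene identifier 16069), which links secreted immunoglobulin into polymers, fell from 6860 ± 1630 to 2110 ± 492 CPM (SD, n = 5 each; -1.70, SE 0.39, adjusted p = 0.00835). The plasma cell regulators Prdm1 (12142) and Xbp1 (22433) fell by 1.44 (SE 0.24, adjusted p = 0.000884) and by 1.61 (SE 0.33, adjusted p = 0.00353). The surface proteoglycan Sdc1 (20969) fell from 67.1 ± 11.6 to 20.6 ± 4.07 CPM (SD, n = 5 each). Bhlha15, a factor of secretory cells, fell by 2.02 (SE 0.39) and the translocon gene Tram2 by 2.08 (SE 0.47). Of 16 plasma cell genes 13 fell (14 adjusted over the list alone) with a median of -1.40, and the list had adjusted p = 1.17e-13 at the preset and adjusted p = 0.249 with an estimated correlation. Of 18 genes of the unfolded protein response 9 fell (12 adjusted over the list alone; median -0.67; adjusted p = 6.69e-08, adjusted p = 0.439 with an estimated correlation), among them Sel1l (-1.11, SE 0.24) and Herpud1 (-1.13, SE 0.27).

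**Figure D2:**
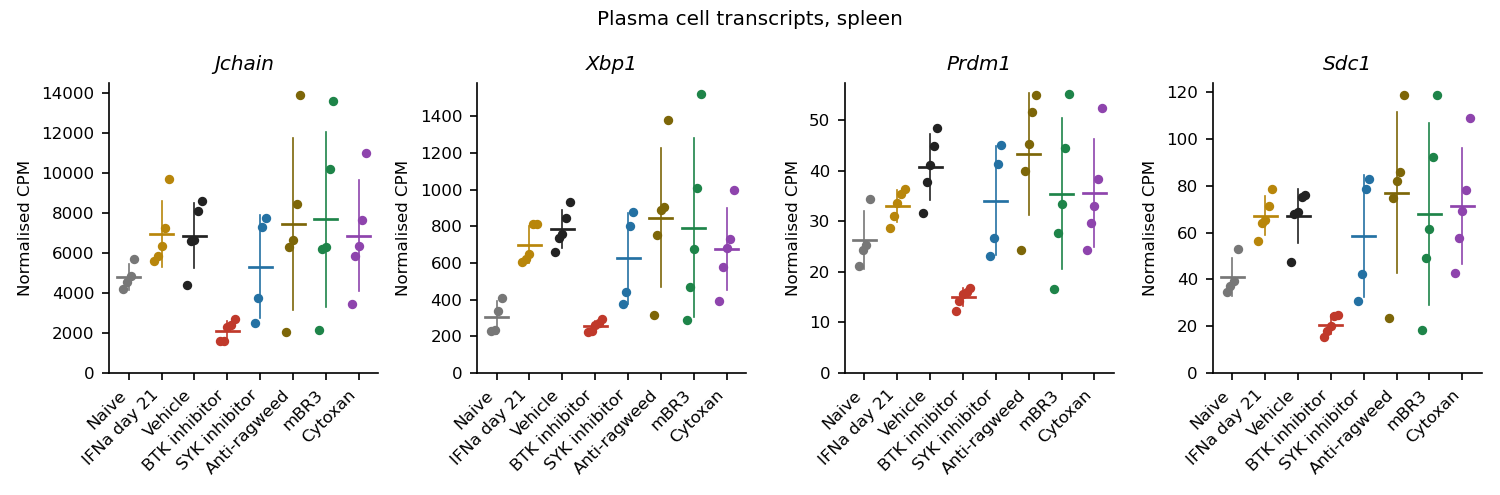
Normalised CPM of Jchain, Xbp1, Prdm1 and Sdc1 in each spleen library on linear vertical axes from 0, by treatment group, with lines at group means and whiskers of 1 SD. BTK inhibitor spleens average 2110 CPM for Jchain and 257 CPM for Xbp1, against 6860 and 786 CPM with vehicle.

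B lymphocyte genes did not move as a list: 1 rose and 1 fell of 18 (1 and 1 adjusted over the list alone; median -0.06; adjusted p = 0.796 at the preset). The complement receptor Cr2 rose by 1.48 (SE 0.39) and the immunoglobulin M receptor Fcmr fell from 269 ± 98.8 to 118 ± 30 CPM. Cd79a stood at 487 ± 82.4 against 439 ± 152 CPM (SD, n = 5 each; 0.15, SE 0.24, adjusted p = 0.768). Btk itself stood at 114 ± 7.86 against 134 ± 22.1 CPM (-0.23, SE 0.12, adjusted p = 0.262). Macrophage genes fell in 6 of 22 cases (12 adjusted over the list alone; adjusted p = 1e-08, adjusted p = 0.249 with an estimated correlation), from Vsig4 at 12.8 ± 5.47 to 0.723 ± 0.281 CPM (SD, n = 5 each; -4.13, SE 0.49) to the growth factor receptor Csf1r (-0.76, SE 0.13). Natural killer and cytotoxic genes rose in 6 of 14 cases (8 adjusted over the list alone; adjusted p = 1.47e-06, adjusted p = 0.249 with an estimated correlation), including the receptor Klre1 (1.24, SE 0.20) and Prf1, which encodes perforin (0.91, SE 0.17). T cell genes rose in 2 of 16 (8 adjusted over the list alone; adjusted p = 8.18e-06 at the preset) and dendritic cell genes in 4 of 13 (4 adjusted over the list alone; adjusted p = 0.0178 at the preset), each with adjusted p = 0.652 with an estimated correlation. They include Cd8a (1.33, SE 0.39) and Cd209a (3.63, SE 0.78). Adipose genes moved with them, with 2 of 9 higher (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.652 with an estimated correlation) and Adipoq at 4.45 ± 3.31 against 0.458 ± 0.202 CPM (SD, n = 5 each).

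Interferon targets in these spleens had 0 of 30 called by edgeR, with a median of 0.19, adjusted p = 0.0425 at the preset and adjusted p = 0.852 with an estimated correlation. Their mean log2 CPM in treated mouse 389 stood apart from its group (7.54 against 8.23 to 8.50). The follicular helper list fell in 2 of 10 cases, Il21 (-1.75, SE 0.46) and Tnfrsf4 (-0.86, SE 0.27), and activation genes in 2 of 19, Fos (-1.36, SE 0.30) and Cd86 (-0.46, SE 0.12). Complement and Fc receptor genes fell in 2 of 14, Fcgr4 (-1.57, SE 0.33) and Fcgr3 (-1.06, SE 0.20), and chemokines in 2 of 17, Ccl8 (-3.64, SE 0.68) and Il1b (-1.36, SE 0.32). Adjusted over the list alone, these counts were 2, 3, 6 and 2, and the complement list had adjusted p = 0.0123 at the preset and adjusted p = 0.652 with an estimated correlation. Fibrosis genes gave 1 higher and 1 lower of 22, Acta2 (1.07, SE 0.21) and Mmp14 (-0.65, SE 0.19), and p53 targets 1 lower of 17, Trp53inp1 (-1.12, SE 0.28). Germinal centre, B cell receptor signalling, neutrophil, erythroid, basophil, platelet, proliferation, tubular injury, podocyte, proximal tubule, distal nephron, mitochondrial, pancreas and adrenal genes gave no call by edgeR, with medians between -0.55 (adrenal) and 2.15 (pancreas). The proximal tubule median of -0.04 and the podocyte median of -0.02 had means of the other sign, 0.09 and 0.01. In all, 348 genes rose and 680 fell. The count of 1028 was 530, 610, 574 and 657 without treated mice 363, 376, 381 and 389, and 664, 658 and 553 without vehicle mice 377, 398 and 399.

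Kidneys of treated mice had far fewer transcripts of tubular injury and inflammation than vehicle kidneys. Lcn2 fell from 306 ± 187 to 12.5 ± 3.06 CPM (SD, n = 5 each; -4.62, SE 0.97, adjusted p = 0.00178). Havcr1 (gene identifier 171283), the kidney injury molecule of the proximal tubule, fell from 284 ± 158 to 59.8 ± 17.1 CPM (SD, n = 5 each), and Spp1 (20750) from 11800 ± 4110 to 2420 ± 139 CPM. The neutrophil attractant Cxcl1 (14825) fell by 5.44 (SE 1.04, adjusted p = 0.000941), the stress cytokine Gdf15 (23886) by 3.54 (SE 0.58, adjusted p = 0.000352), and Grem1, an antagonist of bone morphogenetic proteins, by 4.48 (SE 0.81). Tubular injury genes fell in 11 and rose in 1 of 16 cases (15 and 1 adjusted over the list alone; median -1.77; adjusted p = 9.05e-06, adjusted p = 0.621 with an estimated correlation). Immediate early genes fell in 11 of 18 (12 adjusted over the list alone), with Egr1 at 8.92 ± 5.6 against 85 ± 39.5 CPM (SD, n = 5 each) and Ier3 down 2.41 (SE 0.32). They had adjusted p = 1.6e-06 at the preset and adjusted p = 0.621 with an estimated correlation. Fibrosis genes fell in 11 of 22 (16 adjusted over the list alone), including Fn1, which encodes fibronectin (-1.56, SE 0.37). The p53 targets fell in 7 of 17 (10 adjusted over the list alone), including the cell cycle inhibitor Cdkn1a (-1.82, SE 0.34). Both had adjusted p = 0.621 with an estimated correlation, from 4.9e-06 and 7e-05 at the preset.

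**Figure D3:**
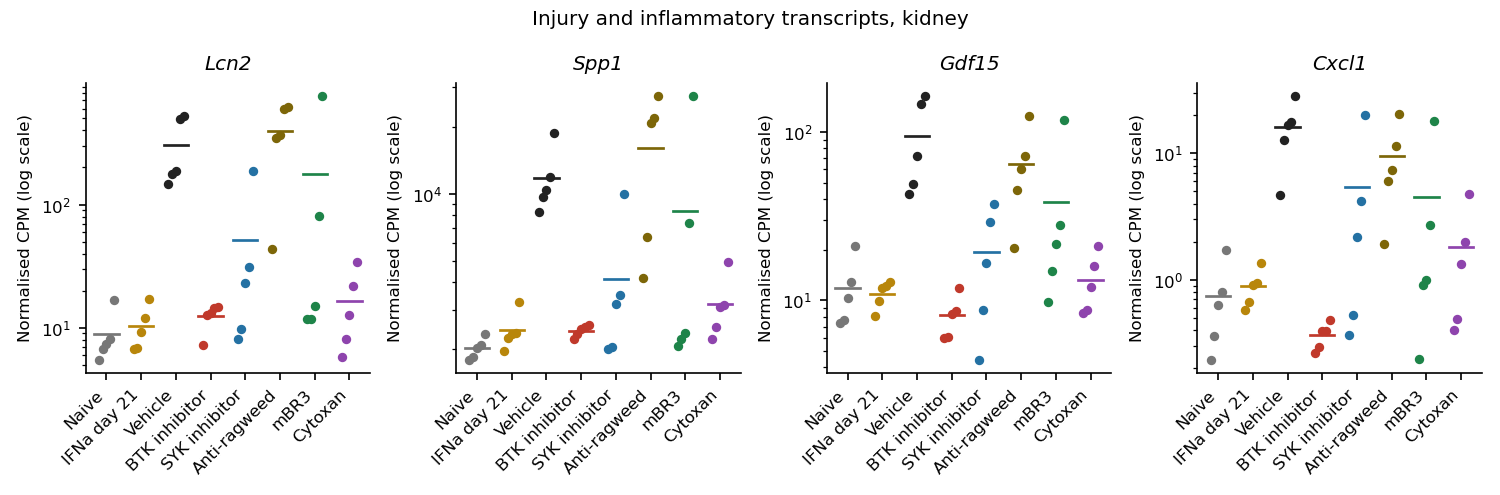
Normalised CPM of Lcn2, Spp1, Gdf15 and Cxcl1 in each kidney library on log-scaled vertical axes, by treatment group, with lines at group means. BTK inhibitor kidneys average 12.5 CPM for Lcn2 and 2420 CPM for Spp1, against 306 and 11800 CPM with vehicle and 8.93 and 2030 CPM in naive mice.

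Proliferation genes fell in 12 of 20 kidney cases (18 adjusted over the list alone). Chemokines fell in 10 of 18 (11 adjusted over the list alone), with Ccl2 at 4.62 ± 1.26 against 18.8 ± 8.85 CPM (SD, n = 5 each), as did macrophage genes in 8 of 21 with 1, Csf1r, higher (10 and 1 adjusted over the list alone). Their adjusted p of 1.56e-05, 0.000729 and 0.00179 at the preset became adjusted p = 0.635, adjusted p = 0.635 and adjusted p = 0.723 with an estimated correlation. Part of the mitochondrial and proximal tubule genes were higher. Mitochondrial genes rose in 11 of 20 cases (13 adjusted over the list alone; adjusted p = 1.81e-06, adjusted p = 0.621 with an estimated correlation). Proximal tubule genes rose in 7 of 21 (9 adjusted over the list alone; adjusted p = 4.9e-06, adjusted p = 0.635 with an estimated correlation), with the water channel Aqp1 at 2110 ± 265 against 881 ± 393 CPM (SD, n = 5 each) and the gluconeogenic enzyme Pck1 up 1.46 (SE 0.42). The distal nephron list was mixed, with 5 higher and 3 lower of 14 (6 and 3 adjusted over the list alone): Pvalb rose by 3.02 (SE 0.64) and the sodium channel subunit Scnn1b fell by 0.90 (SE 0.18). Cck, Tnn and Serpina6 rose by 4.19 (SE 0.69), 4.17 (SE 0.70) and 3.31 (SE 0.63). Podocyte genes gave 2 higher and 1 lower of 15, with Nphs1, which encodes nephrin, at 36.5 ± 16.7 against 16.4 ± 9.08 CPM (SD, n = 5 each). Adrenal genes moved with all of these: 1 of 8 fell (2 adjusted over the list alone; median -2.28; adjusted p = 0.635 with an estimated correlation). Cyp11b1 was between 0.0409 and 76.8 CPM of library total in treated and between 35.8 and 273 in vehicle kidneys. With the adrenal covariate 11 of the 16 injury genes fell, with a median of -2.12, as did 11 chemokines and 8 macrophage genes. The mitochondrial and proximal tubule genes that rose went from 11 to 7 and from 7 to 4, with medians of 0.45 and 0.59.

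Interferon targets had 0 of 30 called by edgeR in treated kidneys, with a median of -0.39. Their mean log2 CPM in treated mouse 389 stood apart from its group (4.89 against 6.10 to 6.33). None of the B lymphocyte, follicular helper, neutrophil, T cell, natural killer, dendritic, platelet or adipose genes passed. B cell receptor signalling genes fell in 5 of 17 cases and rose in 0 (5 lower and 1 higher adjusted over the list alone; median -0.55; adjusted p = 0.0186, adjusted p = 0.723 with an estimated correlation), complement in 2 of 14, plasma cell in 2 of 15, the unfolded protein response in 2 of 18 and germinal centre genes in 1 of 7. In turn 3 of 15 erythroid, 1 of 9 pancreas and 1 of 4 basophil genes rose. For the plasma cell and unfolded protein lists the median was 0.01 and the mean and test negative. For germinal centre genes the median was 0.15 with mean and test negative, and for erythroid genes -0.05 with mean and test positive. Btk stood at 0.905 ± 0.212 against 1.85 ± 1.04 CPM (SD, n = 5 each; adjusted p = 0.128). In all, 1960 genes rose and 2043 fell. The count of 4003 was 1923 and 2622 without vehicle mouse 377 and treated mouse 389, and it also fell by more than a factor of 1.5 without vehicle 399. These kidneys were also compared with naive and interferon kidneys, a comparison added after the data were seen. Against naive kidneys, 265 genes rose and 109 fell, 28 of 30 interferon targets rose with a median of 2.58, and 0 of 16 injury genes were called by edgeR with a median of 0.10 (1974 genes of the whole comparison had an unadjusted p under 0.05). Against interferon kidneys, 22 genes rose and 10 fell, with 0 injury and 0 interferon genes called and medians of 0.09 and -0.05.

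The change under the BTK inhibitor differed between the tissues for 1457 genes, 731 with the higher value in spleen. Txndc5, a chaperone of secretory cells, changed by -1.37 in spleen and 0.14 in kidney, a difference of -1.52 (SE 0.19, adjusted p = 0.000122). Lcn2 changed by 0.48 and -4.62, a difference of 5.08 (SE 0.63, adjusted p = 0.000115), and Csf1r by -0.76 and 0.89, a difference of -1.64 (SE 0.23, adjusted p = 0.000241). For Sdc1, which fell in both, the difference was -0.53 (SE 0.35, adjusted p = 0.391). Of 16045 genes tested in both tissues 247 were called in both, where 211 would be if the tissues were independent, and 193 of them moved the same way. With the mouse as a block 1361 genes differed. The count was 792, 829, 962 and 908 without treated mice 363, 376, 389 and 414, and 937, 884 and 2100 without vehicle mice 398, 399 and 267.

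In blood, BTK inhibitor treatment lowered 10 genes and raised 2. Cd14 (gene identifier 12475), the monocyte receptor for lipopolysaccharide, fell from 6.69 ± 1.46 to 1.83 ± 0.879 CPM (SD, n = 5 each; -1.88, SE 0.36, adjusted p = 0.0191), and Prdx1, a peroxidase, by 1.79 (SE 0.33). Macrophage genes fell in 1 of 20 cases (6 adjusted over the list alone; mean -1.25; adjusted p = 7.47e-07 at the preset, adjusted p = 0.162 with an estimated correlation). No T cell or natural killer gene passed over all genes, and 3 of 16 and 6 of 13 were higher adjusted over the list alone (adjusted p = 0.241 and adjusted p = 0.267 with an estimated correlation). Btk stood at 4 ± 0.986 against 4.33 ± 0.528 CPM (adjusted p = 0.835). The count of 12 was 0 without treated mouse 363, 376 or 389 or vehicle 432. It was 147, 73 and 3 without vehicle 417, 391 and 418, and 0 without blood 419 and 432, an alternative chosen after seeing the data. DESeq2 called 127 genes and limma voom 154.

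The SYK inhibitor, which blocks the kinase next to BTK below the B cell receptor, was compared with vehicle. In the spleen 3 genes passed, and they are named after their values were seen because so few did. The chemokine receptor Cxcr4 (gene identifier 12767) fell from 268 ± 55.3 (SD, n = 5) to 121 ± 8.24 CPM (SD, n = 4; -1.15, SE 0.21, adjusted p = 0.0318), Dph5 of diphthamide synthesis rose by 0.60 (SE 0.11) and 1 gene without a symbol fell. Natural killer and cytotoxic genes had 0 calls over all genes and 7 of 14 higher adjusted over the list alone (median 0.46; adjusted p = 7.95e-12, adjusted p = 0.0293 with an estimated correlation). Plasma cell genes had 0 of 16 called by edgeR, a median of -0.23, adjusted p = 0.00301 at the preset and adjusted p = 0.738 with an estimated correlation. Syk stood at 452 ± 80.3 against 483 ± 132 CPM (SD, n = 4 and 5; -0.10, SE 0.20, adjusted p = 1). The pancreas gene Clps was at 61.3 ± 54.2 against 5.27 ± 7.18 CPM of library total (SD, n = 4 and 5). No pancreas gene passed (0 of 10 by edgeR, 0 adjusted over the list alone; median 3.62; adjusted p = 3.28e-07, adjusted p = 0.626 with an estimated correlation). DESeq2 called 49 genes, limma voom 300, a fit of both groups alone 0, and the fit with a pancreas covariate 0.

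In kidneys of SYK inhibitor mice, 1574 genes rose and 1456 fell. Cdkn1a fell from 91.9 ± 52.2 to 32.2 ± 9.33 CPM (SD, n = 5 each), Gdf15 by 2.31 (SE 0.55), Clu by 1.76 (SE 0.47) and Grem1 by 4.58 (SE 0.82). Lcn2 stood at 51.9 ± 76.3 against 306 ± 187 CPM (SD, n = 5 each; -2.56, SE 0.88, adjusted p = 0.0414). Injury genes fell in 6 and rose in 1 of 16 cases (9 and 1 adjusted over the list alone) and p53 targets fell in 7 of 17 (7 adjusted over the list alone). Transcripts of spleen and blood cells rose with them: B lymphocyte genes in 14 of 17 cases (15 adjusted over the list alone), erythroid in 13 of 15 (14 adjusted over the list alone), neutrophil in 8 of 9 (9 adjusted over the list alone) and platelet genes in 5 of 8 (6 adjusted over the list alone). These 6 lists had adjusted p between 5.25e-06 and 0.000703 at the preset and adjusted p = 0.582 with an estimated correlation. Of the adrenal genes 1 of 8 fell (2 adjusted over the list alone; median -2.80; adjusted p = 0.000706, adjusted p = 0.582 with an estimated correlation). Pancreas genes rose in 2 of 9 cases (7 adjusted over the list alone; median 2.45; adjusted p = 0.0452, adjusted p = 0.582 with an estimated correlation). Cd79a was at 6.95 ± 6.03 against 1.43 ± 1.09 CPM of library total (SD, n = 5 each). Without the 3 of 5 kidneys that carry them, of mice 252, 268 and 356, left out after seeing the data, 2 genes were called. A fit with so few treated kidneys can call fewer genes for that reason alone. The fall from 3030 therefore does not show what caused the calls. Splits of the same 10 kidneys gave as many genes in 6 of 100 cases, so chance is not excluded. The count of 3030 was 744, 1183 and 4085 without vehicle 377, 399 and 267 and 1826 and 1829 without SYK inhibitor 268 and 356. It was also far lower in a fit of both groups alone, as given below. In blood, edgeR called 0 genes, with 893 at an unadjusted p under 0.05, DESeq2 called 4, and leaving out vehicle 391 or 417 gave 9 or 1.

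Both inhibitors were given, at 100 and 60 mg/kg, so the doses differ and the direct comparison is of the groups as treated. Plasma cell genes were lower with the BTK than with the SYK inhibitor in 4 of 16 cases in the spleen (13 adjusted over the list alone; median -1.20; adjusted p = 4.29e-09, adjusted p = 0.631 with an estimated correlation), with Prdm1 at 15 ± 1.81 (SD, n = 5) against 34.1 ± 10.8 CPM (SD, n = 4; -1.18, SE 0.25, adjusted p = 0.0196). Fcrl5, an Fc receptor-like protein of B cells, was lower by -1.86 (SE 0.35) and Vsig4 by -2.62 (SE 0.50). In all, 15 spleen genes were higher and 102 lower. The count of 117 was 16, 18 and 71 without SYK inhibitor mice 251, 252 and 374 and 25, 19, 35 and 47 without BTK inhibitor mice 363, 376, 381 and 389. Under the other alternatives it ran from 31 with a pancreas covariate to 4150 with limma voom. In the kidney 22 genes were higher and 334 lower with the BTK inhibitor, 15 of 17 B lymphocyte genes among the latter (15 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation) and 7 of 9 neutrophil genes (9 adjusted over the list alone; adjusted p = 0.0884 with an estimated correlation). Just 1 gene was called without the kidneys of mice 252, 268 and 356, which also left fewer SYK inhibitor kidneys to test. None of the 16 injury genes was called, with a median of -0.49. Splits of these kidneys gave as many in 7 of 100 cases. The count of 356 was 13, 80, 74, 42 and 47 without BTK inhibitor mice 389, 363, 376, 381 and 414, and 24, 192 and 1222 without SYK inhibitor mice 268, 356 and 374. In blood 20 genes were lower and 0 higher, among them Fcmr (-1.89, SE 0.39), Cd14 (-1.76, SE 0.36) and Clec4e (-2.09, SE 0.42). The count ran from 1 without BTK inhibitor mouse 376 to 75 without SYK inhibitor mouse 356.

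The changes against vehicle under both inhibitors correlated across genes in all tissues, which a shared vehicle group produces by itself. In the kidney r was 0.747, against 0.5 in simulations with a shared control and no effect of either drug. It was 0.55 when each inhibitor had its own vehicle mice. In the spleen r was 0.401, below the simulated 0.468, and 0.0721 with vehicles split, while the covariance of 0.0545 was above the simulated 0.038. In blood it was 0.617 against 0.509, and 0.123 with vehicles split. The simulations also left out effects of 1 drug alone, so they do not give the r expected here without a shared effect. Genes are not independent replicates, and these 3 relations carry no p. In the kidney 1880 genes were called under both inhibitors, 913 lower and 966 higher in both, a count that the shared vehicle mice also raise and for which no value without a shared effect was computed.

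Mice given mBR3 were compared with mice given anti-ragweed, an antibody labelled with the same isotype. B lymphocyte genes in the spleen fell in 15 of 18 cases (16 adjusted over the list alone; median -1.03; adjusted p = 4.97e-10, adjusted p = 0.572 with an estimated correlation). Ebf1 (gene identifier 13591), a factor of B cell identity, fell from 22.6 ± 7.83 to 4.64 ± 1.59 CPM (SD, n = 5 each; -2.28, SE 0.30, adjusted p = 2.64e-05), and Cd79a (12518) from 445 ± 132 to 232 ± 80.8 CPM. The BAFF receptor gene Tnfrsf13c fell by 0.72 (SE 0.23), and Tnfsf13b, which encodes BAFF, rose by 0.67 (SE 0.16). B cell receptor signalling genes fell in 6 of 17 (8 adjusted over the list alone; adjusted p = 0.000633, adjusted p = 0.803 with an estimated correlation), among them Syk (-0.71, SE 0.19) and Btk (-0.38, SE 0.12). Neutrophil genes rose in 14 of 16 cases (15 adjusted over the list alone; median 2.74; adjusted p = 3.45e-16, adjusted p = 0.113 with an estimated correlation), with S100a9 at 340 ± 239 against 49.2 ± 19.1 CPM (SD, n = 5 each). Basophil and mast cell genes rose in 5 of 9 (6 adjusted over the list alone; adjusted p = 0.000633, adjusted p = 0.113 with an estimated correlation). No plasma cell gene was called (0 of 16 by edgeR; median -0.03). Clps of the pancreas was at 79.6 ± 84.8 against 26.1 ± 29 CPM of library total.

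**Figure D4:**
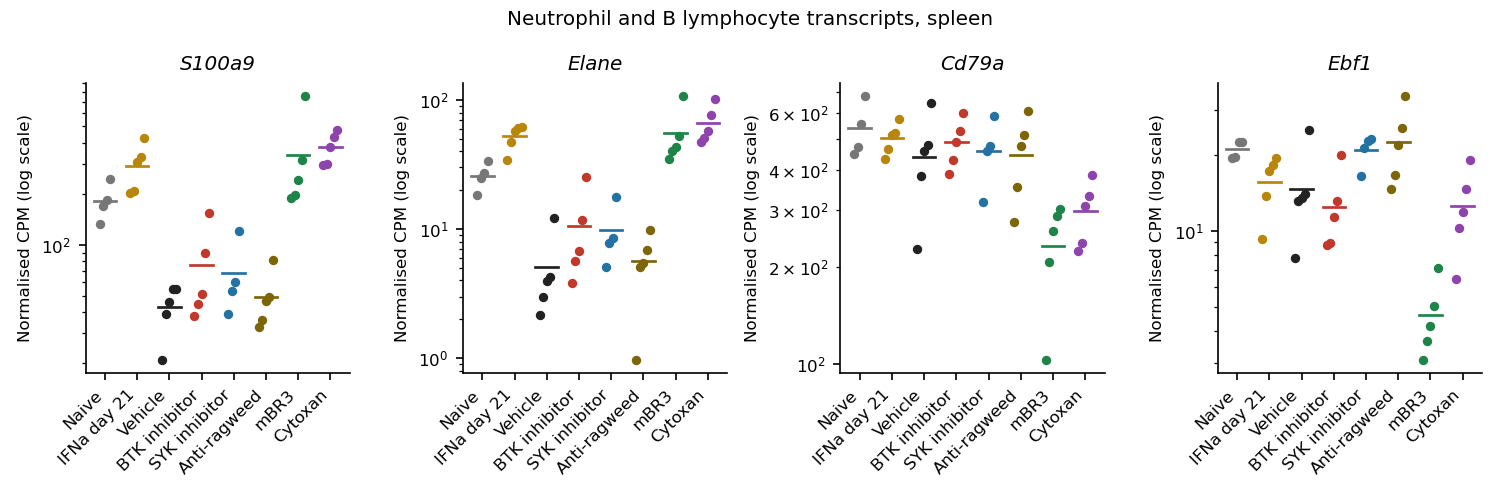
Normalised CPM of S100a9, Elane, Cd79a and Ebf1 in each spleen library on log-scaled vertical axes, by treatment group, with lines at group means. S100a9 averages 340 CPM with mBR3 and 377 CPM with Cytoxan, against 49.2 CPM with anti-ragweed and 43.2 CPM with vehicle, and Ebf1 averages 4.64 CPM with mBR3 and 22.6 CPM with anti-ragweed.

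In all, 1296 spleen genes rose and 2228 fell with mBR3. The spleen count of 3524 rests on the pooled spread of the 8 groups: both groups alone gave 38, and leaving out anti-ragweed 273, 379 and 382 gave 1266, 1288 and 5671. In the kidney 1 gene passed, Hhatl (gene identifier 74770), named after its value was seen because it is the only gene (1.11, SE 0.19, adjusted p = 0.033). Injury genes had 0 of 16 called by edgeR (4 lower adjusted over the list alone), a median of -0.89, adjusted p = 4.44e-05 at the preset and adjusted p = 0.918 with an estimated correlation. Fibrosis genes had 0 of 22 (6 lower adjusted over the list alone; median -0.61; adjusted p = 6.38e-07, adjusted p = 0.918 with an estimated correlation). DESeq2 called 497 kidney genes and limma voom 6113. Without mBR3 367, anti-ragweed 428 or anti-ragweed 272 edgeR called 2381, 2320 or 1860. Without mBR3 373 it called 2, and without mBR3 255, 364 or 386 or anti-ragweed 379 or 382 it called 0. In blood, with 4 against 2 libraries, the complement receptor Cr2 and the IgE receptor Fcer2a fell by 3.14 (SE 0.56) and by 4.10 (SE 0.77). In the list 13 of 18 B lymphocyte genes fell adjusted over the list alone (median -1.62; adjusted p = 4.81e-19, adjusted p = 0.129 with an estimated correlation). The blood count of 2 was at most 1, without mBR3 255, in any fit that left out 1 library.

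Cytoxan was compared with vehicle as a cytotoxic reference. Neutrophil genes rose in 14 of 16 cases in the spleen (16 adjusted over the list alone; median 3.07), with adjusted p = 1.46e-56 at the preset and adjusted p = 8.47e-05 with an estimated correlation. Elane (gene identifier 50701) rose from 5.12 ± 4.07 to 66.6 ± 22.4 CPM (SD, n = 5 each; 3.70, SE 0.52, adjusted p = 3.75e-05), Mpo, which encodes myeloperoxidase, by 3.44 (SE 0.47), and the early granulocyte gene Ms4a3 by 3.74 (SE 0.45). Basophil and mast cell genes rose in 4 of 9 cases (5 adjusted over the list alone; adjusted p = 9.74e-08, adjusted p = 0.00231 with an estimated correlation), led by Prss34 and Mcpt8 (3.44, SE 0.56, and 3.40, SE 0.55). Tsc22d3, a glucocorticoid target, fell by 1.97 (SE 0.39) and Vsig4 by 1.86 (SE 0.42). Plasma cell and B lymphocyte genes had 0 of 16 and 0 of 18 called by edgeR, with medians of -0.08 and -0.41. The lists had adjusted p = 0.595 and adjusted p = 0.001 at the preset, and adjusted p = 0.91 and adjusted p = 0.71 with an estimated correlation. Proximal tubule genes rose in 2 of 18 (10 adjusted over the list alone; adjusted p = 0.586 with an estimated correlation), and 3 of the 5 Cytoxan spleens carry the run code of most kidneys. In all, 74 genes rose and 49 fell. The count of 123 was 33 with a run code term and 33 without those 3 spleens, which also left fewer Cytoxan spleens to test. It was 69, 80 and 190 without Cytoxan 411, 369 and 365 and 212 and 81 without vehicle 267 and 391.

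Cytoxan kidneys had 2370 genes higher and 2521 lower than vehicle kidneys. Proximal tubule genes rose in 16 of 21 cases (17 adjusted over the list alone; median 0.89), with Pck1 (gene identifier 18534) at 2690 ± 850 against 530 ± 220 CPM (SD, n = 5 each; 2.35, SE 0.43, adjusted p = 0.000495). Mitochondrial genes rose in 15 of 20 (16 adjusted over the list alone) and podocyte genes in 7 of 15 with 1 lower (10 and 1 adjusted over the list alone), with Nphs1 up 1.66 (SE 0.42). Injury genes fell in 9 of 16 cases (12 lower and 1 higher adjusted over the list alone), with Lcn2 at 16.6 ± 11.6 CPM, and fibrosis genes in 12 of 22 (14 adjusted over the list alone). These 5 lists had adjusted p between 1.7e-07 and 0.00332 at the preset and adjusted p = 0.663 with an estimated correlation. Cyp11b1 was at 51.6 ± 61.1 against 132 ± 104 CPM of library total (SD, n = 5 each). With a run code term, since 3 of these kidneys have another code, 1193 genes were called in place of 4891. In blood, edgeR called 0 genes, with 677 at an unadjusted p under 0.05, and DESeq2 called 13. The unfolded protein list had 6 of 18 lower adjusted over the list alone (median -0.54; adjusted p = 0.00517 with an estimated correlation) and the neutrophil list 7 of 13 higher (median 1.09; adjusted p = 0.00818 with an estimated correlation). Chemokine genes had 2 of 8 higher adjusted over the list alone, with a median of 0.46, a mean of -0.01 and a positive test (adjusted p = 0.0434 with an estimated correlation).

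A score gave each library's position on the anti-ragweed against naive signature, of 469 raised and 260 lowered genes in spleen and 1270 and 656 in kidney. Whether anti-ragweed mice received the interferon adenovirus is not stated, so disease and virus are not separated in this score. The BTK inhibitor lowered the score in spleen from 3.61 ± 0.26 to 2.46 ± 0.44 (SD, n = 5 each). In kidney it lowered the score from 0.71 ± 0.70 to -1.59 ± 0.41. In both tissues 5 of 5 mice lay below all vehicle mice. Cytoxan lowered it to 2.92 ± 0.21 and -1.25 ± 0.25, and the SYK inhibitor in kidney to -0.90 ± 0.60. Each of these 5 differences had an exact permutation p = 0.00794, the smallest 5 against 5 mice allow, and an adjusted p = 0.0127. Adrenal transcripts differed between these groups too, and the kidney score was not adjusted for them. Cyp11b1 averaged 62.4 and 0.0737 CPM of library total in anti-ragweed and naive kidneys. It averaged 25.9 and 132 CPM in BTK inhibitor and vehicle kidneys. The SYK inhibitor spleens had 3.28 ± 0.23 (SD, n = 4; exact permutation p = 0.0952, adjusted p = 0.127). On the vehicle against naive signature, mBR3 mice had 3.29 ± 0.98 against 3.73 ± 0.47 in spleen (exact permutation p = 0.46) and -0.27 ± 1.35 against 0.78 ± 0.85 in kidney (exact permutation p = 0.183, adjusted p = 0.209). On that signature naive mice lay at 0.96 ± 0.23 in spleen (SD, n = 4) and -2.08 ± 0.14 in kidney. On the anti-ragweed signature they lay at 0.85 ± 0.26 and -2.40 ± 0.13. Interferon mice lay at 2.58 ± 0.33 and -1.77 ± 0.22 on the anti-ragweed signature, near the BTK inhibitor mice in both tissues. With the 100 signature genes of smallest p the spleen differences were -0.70 for the BTK inhibitor and -0.39 for Cytoxan, no longer past the threshold (adjusted p = 0.0635 each, the highest of a range from 0.0127 over the alternatives), and 0.20 for the SYK inhibitor, the other direction. Leaving out vehicle 391 brought the SYK inhibitor spleen difference of -0.33 to -0.43, and leaving out mBR3 367 the kidney difference of -1.05 to -1.59, each past the threshold.

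**Figure D5:**
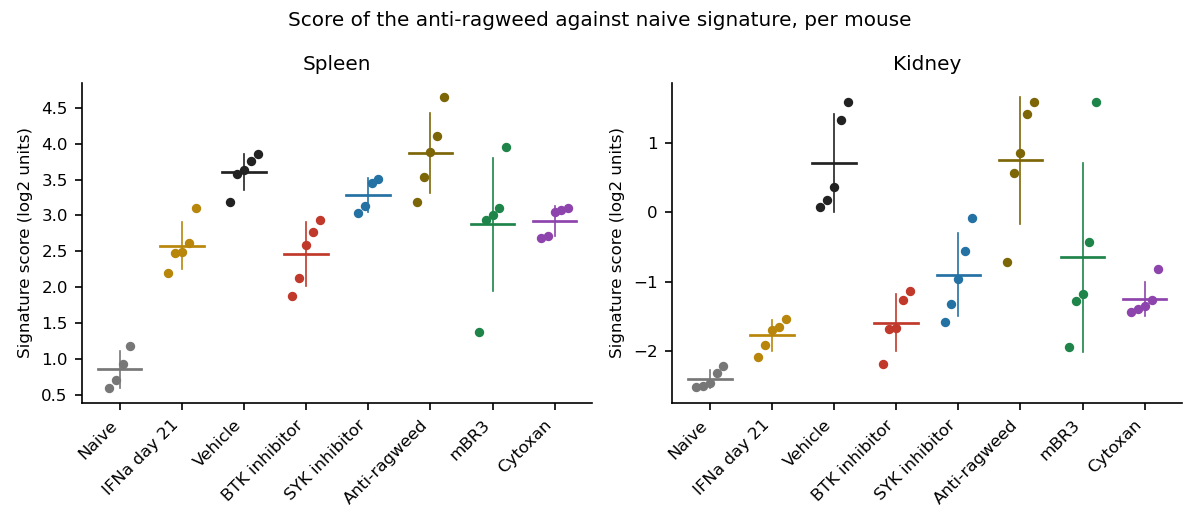
Score of each spleen and kidney library on the anti-ragweed against naive signature, in log2 units on the vertical axis, by treatment group, with lines at group means and whiskers of 1 SD. BTK inhibitor mice average 2.46 in spleen and -1.59 in kidney, between vehicle (3.61 and 0.71) and naive mice (0.85 and -2.40).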

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

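Of the tests in this part, the match of kidney libraries to spleen libraries of their own run code, and the look at the kidneys of mice 268 and 356 apart from that of mouse 252, were chosen only after the result was seen.

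In 101 groups of 4 or 5 libraries, 10 had a library far from the rest of its group by Dixon's test at 95%, where chance alone gives 5.05. Total counts stood apart in blood of interferon mouse 359 (13.85 M against 11.12 to 11.89 M), blood of mBR3 mouse 419 (15.19 against 11.06 to 11.32 M), kidney of anti-ragweed mouse 428 (32.35 against 25.44 to 27.04 M) and spleen of interferon mouse 274 (10.80 against 22.68 to 23.65 M). The mean log2 CPM of interferon targets stood apart in BTK inhibitor mouse 389, low in both spleen (7.54 against 8.23 to 8.50) and kidney (4.89 against 6.10 to 6.33), and in the spleen of anti-ragweed mouse 382 (8.09 against 6.87 to 7.10). The tubular injury score was low in naive kidney 438 (4.20 against 4.47 to 4.55). The proximal tubule score was high in BTK inhibitor kidney 381 (9.33 against 9.06 to 9.12) and low in mBR3 kidney 367 (7.57 against 8.97 to 9.43).

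The effect of the BTK inhibitor differed between spleen and kidney in 1457 genes by the test of the difference itself. By that test the change of Txndc5 was lower in the spleen, and the changes of Lcn2, Gdf15 and Egr1 were lower in the kidney.

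Kidney transcripts appeared in blood libraries that share a run code with kidney libraries. Kap had 6.38 to 19.5 CPM of library total in the 9 blood libraries of run code R2193 and 0 counts in the 27 of R2194. RNA of a mouse's own kidney in its blood would follow the kidney level of its own group. The slope of the blood counts on the ratio of naive to Cytoxan kidney levels was -0.01, with an upper 95% limit of 0.22. Of the 277 genes used, 6 differed 2-fold between those kidney levels. Error in so narrow a ratio also pulls the slope toward 0, so it argues only weakly against the mouse's own kidney. If the code marks a sequencing run, reads carried over from kidney libraries of that run are a candidate explanation. They predict a slope near 0, as seen, but error in the ratio would bring the slope toward 0 too.

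Spleen tissue or RNA of the same mouse would bring all spleen genes into the SYK inhibitor kidneys of mice 252, 268 and 356 at a like share. The ratio of the 75th to the 25th percentile of that share was 14.4 in kidney 252, which argues against its own spleen as the cause in all 3. It was 3.97 in kidney 268, which has no spleen library of its own, and 1.49 in kidney 356, whose share on a wider set of 86 genes varied more against its own spleen (SD 1.29 in log2, 14th of 38) than against spleen 411 of the run code of the kidneys (0.38), but spleen tissue stays open in both. Blood left in the vessels is argued against by levels at least 203 times those predicted from blood. Reads carried over from spleen libraries of the same run are a candidate explanation that stays open: 2 of the 3 kidneys, 252 and 356 (268 and 356 with another gene set), best matched a spleen with the run code of the kidneys, but all 3 such spleens are Cytoxan spleens, so run code and treatment cannot be told apart.

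Tubular injury genes were lower in BTK inhibitor than in vehicle kidneys, and vehicle kidneys held adrenal transcripts. With adrenal transcripts as a covariate the median of the injury genes was -2.12, against -1.77 without, which argues against adrenal tissue as the whole cause. After thinning all libraries to the smallest total, 85.7% of the called genes were called again, which argues against depth. A drug effect on kidney injury is a biological explanation that the design names, and it may hold as a hypothesis, since it was found and tested on the same data. Other technical causes were not tested.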

How the results depend on the processing

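Covariates for adrenal and pancreatic transcripts, leaving out the globin genes and leaving out the named sets of libraries were chosen after seeing the data. Of 190 counts of called genes under alternatives that keep all mice or leave out a set, 125 lay within 1.5 times the reported count, and of 242 that leave out 1 library 129 did. The BTK inhibitor counts against vehicle ran from 793 to 2220 in spleen and from 3131 to 5552 in kidney under the former. Under the latter they ran from 530 to 1073 and from 1923 to 4689. All 45 named spleen genes and all 70 named kidney genes called there kept their direction in 17 settings. Of them, 28 and 49 were called in every setting. These genes were taken because the main fit called them, and the settings share its libraries, so a kept direction is little further support. Counts of every size moved, as with 3030 genes for the SYK inhibitor in kidney and 3524 for mBR3 in spleen, whose lowest counts were 2 and 38. In blood 11% of the 2-fold changes planted in simulated counts were found, which limits what can be seen there. Where no cause is given below, the cause was not tested.

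With the DESeq2 Wald test the counts were as follows. In spleen, 242 for vehicle against interferon, 49 for SYK inhibitor against vehicle, 448 between the inhibitors and 248 for Cytoxan. In kidney, 300 for interferon against naive, 569 between the inhibitors and 497 for mBR3. In blood, 312 for interferon against naive, 167 for vehicle against interferon, 127 for BTK and 4 for SYK inhibitor against vehicle, 144 between the inhibitors, 11 for mBR3 and 13 for Cytoxan. With limma voom and sample weights the spleen counts were 5797 for interferon and 3969 for vehicle against naive, 675 for vehicle against interferon, 2220 for BTK and 300 for SYK inhibitor against vehicle, 4150 between them and 833 for Cytoxan. The voom kidney counts were 3416 for interferon against naive, 1859 for the SYK inhibitor, 6113 for mBR3 and 8726 for Cytoxan, and its blood counts 374 for interferon against naive, 282 for vehicle against interferon, 154 for the BTK inhibitor, 164 between the inhibitors and 4 for mBR3.

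A fit of only the 2 groups compared, which has fewer libraries to estimate the spread, gave in spleen 2126 for interferon against naive, 0 for the SYK inhibitor, 361 between the inhibitors, 38 for mBR3 and 54 for Cytoxan. In kidney it gave 383, 13, 1 and 0 for interferon against naive, the SYK inhibitor, between the inhibitors and mBR3. In blood it gave 255 for interferon against naive, 0 for vehicle against interferon, 3 for the BTK inhibitor, 0 between the inhibitors, 0 for mBR3 and 4 for Cytoxan. A term for the run code gave 33 for Cytoxan in spleen, 1193 for Cytoxan in kidney, and in blood 83 for interferon against naive and 0 for vehicle against naive and against interferon. Anti-ragweed as the control gave 553 for Cytoxan in spleen and 2 in blood. RLE factors gave 3 for mBR3 in kidney and 33 between the inhibitors in blood, the stricter filter 3 for mBR3 in kidney, and no filter 32 between the inhibitors in blood. A pancreas covariate gave 0 for the SYK inhibitor and 31 between the inhibitors in spleen. The next 2 fits kept fewer treated libraries, which can lower a count by itself. Without the 3 Cytoxan spleens of the kidney run the Cytoxan count was 33. Without the SYK inhibitor kidneys of mice 252, 268 and 356 the counts were 2 against vehicle and 1 between the inhibitors. Without blood 419 and 432 they were 25 for vehicle against interferon, 0 for the BTK inhibitor, 51 between the inhibitors and 0 for mBR3. With the 100 signature genes of smallest p the spleen score changed by -0.70 with the BTK inhibitor and -0.39 with Cytoxan, neither past the threshold, and by 0.20, the other direction, with the SYK inhibitor. With vehicles split between the inhibitors the correlations were 0.0721 in spleen, 0.55 in kidney and 0.123 in blood. The mouse as a block gave 1361 in place of 1457 genes for the difference between spleen and kidney. It changed no call among the genes named for that difference.

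Leaving out 1 library gave, in spleen, 419 to 1131 for interferon against naive, 940 to 1656 for vehicle against naive, 44 to 131 for vehicle against interferon, 530 to 1073 for the BTK and 0 to 4 for the SYK inhibitor, 16 to 133 between them, 1266 to 5671 for mBR3 and 69 to 212 for Cytoxan. In kidney, in the same order, the ranges were 131 to 219, 4174 to 5444, 3303 to 5840, 1923 to 4689, 744 to 4085, 13 to 1222, 0 to 2381 and 3668 to 4775. In blood they were 79 to 132, 1249 to 3034, 20 to 447, 0 to 147, 0 to 9, 1 to 75, 0 to 1 and 0 to 0. The difference between spleen and kidney ran from 792 to 2100. The SYK inhibitor spleen score ran from -0.43 to -0.25 and the mBR3 kidney score from -1.59 to -0.70.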

Other observations

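The test of plasma cell against B lymphocyte scores was chosen only after the result was seen, and so was the comparison of BTK inhibitor kidneys with naive and with interferon kidneys in the report.

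Plasma cell transcripts fell in BTK inhibitor spleens without a fall in B lymphocyte transcripts. The mean log2 CPM of plasma cell genes was 6.09 ± 0.18 with the inhibitor and 7.34 ± 0.24 with vehicle (SD, n = 5 each), a change of -1.25, lower in 5 of 5 mice. For B lymphocyte genes it was 7.06 ± 0.32 and 7.03 ± 0.53, a change of 0.04 (exact permutation p = 0.944). The difference between both changes was -1.29, with a 2-sided exact permutation p = 0.00794, the smallest that 5 against 5 mice can give. A fall in the share of B lineage transcripts in general would lower both scores alike and is argued against. The lists had shown this pattern before the test was chosen, so its p adds no support of its own. The scores are relative to the RNA of the whole spleen, so they cannot tell whether the number of B cells fell. Fewer plasma cells, or less secretory activity per cell, could each explain the pattern, and RNA from whole spleen does not separate them.

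If antibody-secreting cells drove kidney injury in each mouse, mice with more plasma cell transcripts in the spleen than their group would have more tubular injury transcripts in the kidney. This was tested in 38 mice with both tissues and was not borne out. The correlation of the deviations from the group means was -0.381 (p = 0.153, from 100000 resamples, 2-sided). The rank correlation was -0.158 (p = 0.437), and r was 0.0272 without the 2 farthest mice and -0.444 without Cytoxan mice.

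Each count of called genes was set against up to 100 splits of the same libraries into groups of the same sizes, the real split being 1 of them. The SYK inhibitor spleen count (3, highest other split 2) was the largest of its splits. It ran from 0 to 4 with 1 library left out, so chance is not excluded there. In the comparisons that follow, the real split called more genes than any other split drawn. In spleen these were interferon against naive (981, 703), vehicle against naive (1631, 942) and vehicle against interferon (103, 0). BTK inhibitor (1028, 161) and BTK against SYK inhibitor (117, 12) were the others. In kidney these were interferon against naive (199, 7), vehicle against naive (5339, 1433) and vehicle against interferon (5238, 2095). BTK inhibitor (4003, 2453), Cytoxan (4891, 1478), and BTK inhibitor against naive (374, 140) and against interferon (32, 0) were the others. In blood these were interferon against naive (150, 1), vehicle against naive (2122, 2054) and BTK against SYK inhibitor (20, 6). The difference of the BTK inhibitor effect between spleen and kidney (1457, 2) was another. A share of 1 in 100 splits is under 0.05 for each comparison alone, but no share is adjusted over the comparisons. Chance is therefore not excluded over all of them. Vehicle against naive in blood called 0 genes with a term for the run code, so treatment and code cannot be told apart. BTK against SYK inhibitor in blood ran from 1 to 75 genes with 1 library left out.

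In 4 further comparisons under 0.05 of the splits called as many genes, but another split called more: mBR3 in spleen (4 of 100 splits as large; 3524, highest other 4799), Cytoxan in spleen (2 of 100; 123, 351), and in blood vehicle against interferon (3 of 100; 72, 1905) and BTK inhibitor (3 of 100; 12, 199). These shares are not adjusted over the comparisons, so chance is not excluded in these 4. The blood split with 1905 genes exchanges interferon mouse 360 and vehicle mouse 391. It keeps the 4 interferon libraries of run code R2193 on one side, as the real split does, so the run code does not tell these splits apart. With a term for that code the real split called 0 genes. Chance cannot be excluded in kidney for the SYK inhibitor (6 of 100; 3030, 4467), BTK against SYK inhibitor (7 of 100; 356, 3308) and mBR3 (21 of 100; 1, 5393). In blood edgeR called 0 genes for the SYK inhibitor (highest other split 2067; 893 genes at an unadjusted p under 0.05; 4 by DESeq2) and for Cytoxan (1; 677; 13), so that all 100 splits had to be as large and the count of splits says nothing about chance there. Splits that call many more genes than the real one, as in kidney between the inhibitors and with mBR3, in blood with the BTK and SYK inhibitors and between vehicle and interferon, and in spleen with Cytoxan, point to a structure of the libraries other than the treatment. In blood it involves vehicle mouse 391, which is moved in the splits with the highest count for vehicle against naive, vehicle against interferon, BTK inhibitor and SYK inhibitor.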
